A study of Homo sapiens with 12 samples.

How the data were processed

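Total RNA of human HA-VSMCs was extracted with Trizol and sequenced on an Illumina protocol, per the labels' protocols. Each of the 12 samples has 1 table with a gene ID, a symbol, a transcript type and an FPKM value per gene. Values are FPKM, fragments scaled for transcript length and library total, as deposited by the authors and per the file headers. The submitters' processing notes name Bowtie 0.12.2 and the mouse genome build mm8, although the sample labels and the gene IDs of the tables are human. Which program made the FPKM values, from which annotation, and how fragments shared by near-identical genes were treated is not given in the sources used here. FPKM scales each gene by transcript length and each library by its total, so a change in a few abundant genes moves all others slightly, and genes with near-identical copies can share fragments. No coordinates are printed, since the build named is not that of the organism.

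Each table listed the same 10593 gene IDs, with 420 further lines per table that name no gene and were left out. Of the IDs, 10541 were found in the NCBI RefSeq gene table of assembly GRCh38.p14, which was used only for current symbols and gene types, and 10451 of them were annotated protein-coding there, among 20056 protein-coding genes of that table. The genes analysed here are therefore a part of the human genes, and counts of changed genes are counts among them. CXXC5 was left out because its value in knockdown replicate 1 is a letter and not a number. Genes on chromosome Y and XIST were left out of every step.

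The number of reads per library is unknown. Whether low values fall at whole multiples of the value of 1 read was checked in 9935 genes, of which 1 showed such steps (a step of 0.205 FPKM in S100A8, with whole multiples judged to within 0.08). Values are rounded to 0.01 in the tables. No relative depth could be derived and no counting interval is given.

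Groups were taken from the sample titles, 3 libraries in each of 4 groups. In the table of knockdown PDGF-BB replicate 3 the value column is headed r4, which does not match its title, and the title was followed. The comparisons, the sharing of all 12 libraries in the fit, the 23 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The planned tests were for read counts. The tables hold FPKM, so the log scale test that fits that unit was used in their place. FPKM values were transformed as log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 libraries were kept, which gave 9613 genes. A linear model with the 4 groups and no replicate term was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend in the variance), over all 12 libraries so that the groups share an estimate of the spread. The contrasts were PDGF-BB in control cells, knockdown without PDGF-BB, knockdown with PDGF-BB, PDGF-BB in knockdown cells, and the interaction, the difference between both PDGF-BB contrasts. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and changes of at least 2-fold are given as a description. The test of differential expression on data simulated with known changes recovered, for PDGF-BB in control cells, 54% of genes changed by 0.25, 98% of those changed by 0.5 and 100% of those changed by 1 on the log2 scale, among 9613 genes with 200 changed. For the interaction it recovered 6%, 92% and 100% of them. Far more than 200 genes passed in the data, which loosens the Benjamini-Hochberg limit, so these shares may understate the recovery there.

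The gene lists cover contractile smooth muscle, extracellular matrix, YAP/TAZ targets, Hippo pathway components, G1/S and DNA replication, mitosis, ERK pathway feedback and targets, cytokines and NF-kB targets, interferon response, cholesterol biosynthesis, glycolysis, ATF4 and amino acid response, p53 targets, proteases and migration, TGF-beta targets, PDGF ligands and receptors, osteochondrogenic genes, ribosomal protein genes and mitochondrially encoded transcripts, with markers of endothelial cells, leukocytes, adventitial fibroblasts and epithelium. Lists with at least 5 tested members, 18 in all, were tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone. JUNB and PDGFRA are in more than 1 list, and markers such as KRT18 and PDGFRA are also expressed by smooth muscle cells in culture.

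Named genes follow a fixed rule. For each pairwise comparison they are the 10 genes with the largest rise and the 10 with the largest fall past the threshold, with a mean log2(FPKM + 1) of at least 3, a protein-coding type and no overlap between the 3 libraries of both groups. For the interaction they are up to 5 genes per direction without the condition on libraries. For each list they are up to 4 members past the threshold with the largest change, or up to 2 if none passed, and for the opposite changes the 5 genes per direction with the largest product of both changes. PTPN14, PDGFRA, PDGFRB, ACTA2, CNN1, TAGLN, MYH11, CCN1, CCN2, CCND1, MKI67 and YAP1 are always named where tested. List members named because they moved against the rest of a short list, and genes said to have been chosen after their values were seen, stand outside the rule.

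Whether the replicate numbers pair the libraries was checked by the correlation of deviations from the group means. For control and knockdown cells without PDGF-BB the 3 same-numbered pairs gave 0.170, 0.204 and 0.255 and the other pairs -0.177 to -0.008, so those libraries were also compared as pairs. That pairing comes from the values, as the labels give only a number. In the other 3 pairs of groups at least 1 same-numbered pair lay under 0.1.

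Libraries were compared before they were averaged, and no pair of a group had over 0.74% identical values. The alternatives tried were median-ratio scaling of the libraries, no filter on low values, a fit of only the 6 libraries compared, a replicate term, a stricter threshold, leaving out each library in turn and, added after the data were seen, a replicate term for the libraries without PDGF-BB only, a pseudocount of 0.1 and an adjustment over all 20056 protein-coding genes with unlisted genes at a p of 1. Overlaps between comparisons that share libraries were set beside 100 simulations of unchanged groups. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.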

Results

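Gene expression was measured by RNA sequencing in human HA-VSMCs, a name commonly used for human aortic vascular smooth muscle cells. The cells received a control siRNA or an siRNA against PTPN14, and were then kept for 24 h with or without PDGF-BB, a growth factor that acts on smooth muscle cells through the PDGF receptors. The 4 groups of control cells, control cells with PDGF-BB, knockdown cells and knockdown cells with PDGF-BB held 3 libraries each, 12 in all. The deposited values are FPKM, fragments scaled for transcript length and library total. They summed to between 341668 and 366459 per library. The number of reads behind each library is unknown, so no counting intervals are given. Means and SDs rest on the 3 libraries of a group, and standard errors and p-values of comparisons on a spread estimated from all 12. The libraries of a group correlated with each other at Pearson values of 0.9954 to 0.9977 across genes. The first principal component, with 70.4% of the variance, separated the libraries with PDGF-BB from those without it. The second, with 18.3%, separated the knockdown from the control libraries. Of the 9613 genes tested, 8820 (91.8%) had an overall p under 0.05 between the 4 groups. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

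PTPN14, the siRNA target (gene ID 5784), encodes a non-receptor protein tyrosine phosphatase that binds the Hippo pathway effector YAP. Its level in the 3 control libraries was 7.51, 7.48 and 7.46 FPKM, and in the 3 knockdown libraries 2.37, 2.44 and 2.48 FPKM. With PDGF-BB it was 4.93, 5.38 and 5.18 FPKM in control cells and 1.69, 1.73 and 1.94 FPKM in knockdown cells. All 6 libraries with the PTPN14 siRNA thus lay below all 6 with the control siRNA. On the log2(FPKM + 1) scale PTPN14 fell by 1.31 after knockdown without PDGF-BB (SE 0.06, limma adjusted p = 1.74e-09) and by 1.15 with it (SE 0.06, limma adjusted p = 2.63e-09). PDGF-BB itself lowered PTPN14 in control cells, with a log2 fold change of -0.46 (SE 0.06, limma adjusted p = 4.47e-06), and in knockdown cells, with -0.30 (SE 0.06, limma adjusted p = 0.000505). All fold changes below are on this log2 scale, which understates the change of genes with low FPKM. Genes called the largest or next in a comparison are so among protein-coding genes with a mean log2(FPKM + 1) of at least 3.

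The first comparison asked which genes PDGF-BB changed in cells with the control siRNA. AREG, a ligand of the EGF receptor, rose from 0.273 ± 0.165 to 119.9 ± 7.34 FPKM (SD, n = 3), a log2 fold change of 6.58 (SE 0.10, limma adjusted p = 6.84e-16). IL11, a cytokine of the interleukin 6 family, rose from 5.76 ± 0.899 to 385 ± 22.9 FPKM (SD, n = 3; log2 fold change 5.84, SE 0.09). IL33, another cytokine, rose from 2.78 to 119.9 FPKM. Among the other largest rises were the cytokine IL24 (5.55), the orphan nuclear receptors NR4A1 (4.52) and NR4A2 (3.94), and PTGS2 (4.20), the inducible enzyme of prostaglandin synthesis. The largest fall was in ADH1B, an alcohol dehydrogenase, from 82.3 ± 6.07 to 3.18 ± 0.482 FPKM (SD, n = 3; log2 fold change -4.32, SE 0.10). CCN2, a matricellular protein and YAP/TAZ target, fell from 272 ± 9.63 to 32.4 ± 1.08 FPKM (SD, n = 3; log2 fold change -3.03, SE 0.05), and PTX3 (-3.02) and the matrix protein THBS1 (-2.86) fell with it.

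Smooth muscle actin ACTA2 fell from 169 ± 12.2 to 58.7 ± 3.63 FPKM (SD, n = 3) with PDGF-BB in control cells, a log2 fold change of -1.51 (SE 0.06, limma adjusted p = 1.3e-11). Of the 20 tested genes of the contractile smooth muscle list, 12 fell and 6 rose. LMOD1 (-2.06), TPM1 (-1.23), TAGLN (-1.14) and CNN1 (-0.98) were among the falls. The actin-binding protein smoothelin, SMTN, rose from 16.1 ± 0.985 to 39.5 ± 1.42 FPKM. The list as a whole was lower than the other genes by camera (adjusted p = 0.0219; adjusted p = 0.416 with an estimated correlation). MYH11 and the proliferation marker MKI67 were not analysed here. Of 28 extracellular matrix genes 21 fell, among them THBS1, FBLN1 (-1.64) and COL12A1 (-1.46), and only the glycoprotein TNC rose (0.57) (camera adjusted p = 7.97e-05; adjusted p = 0.188 with an estimated correlation). Of 21 YAP/TAZ targets 16 fell, including CCN2, ANKRD1 (-2.53) and GADD45A (-1.88), whereas IGFBP3 (1.62) and NT5E (1.52) rose (camera adjusted p = 1.19e-05; adjusted p = 0.043 with an estimated correlation). YAP1 itself had a log2 fold change of -0.05 (SE 0.04, limma adjusted p = 0.274). Of 19 Hippo pathway components, YAP1 included, 7 rose and 6 fell, with the largest falls in VGLL3 (-1.92) and FRMD6 (-1.62) and the largest rise in WWTR1 (0.78), the gene of TAZ (camera adjusted p = 0.928).

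Genes that respond to growth factor and inflammatory signals rose with PDGF-BB in control cells. Of 20 genes of the ERK pathway feedback and target list 19 rose, such as the immediate early transcription factors FOS (2.31), EGR1 (2.25) and EGR3 (2.23) (camera adjusted p = 4.63e-07; adjusted p = 0.139 with an estimated correlation). CCND1, which encodes cyclin D1, rose from 97.3 ± 11.2 to 141 ± 5.82 FPKM (SD, n = 3; log2 fold change 0.54, limma adjusted p = 6.79e-06). Of 23 cytokine and NF-kB target genes 17 rose, with IL11, PTGS2, IL1B (4.01) and CSF3 (3.35) at the top, and 5 fell, of which VCAM1 fell by 1.39 (camera adjusted p = 1.15e-05; adjusted p = 0.201 with an estimated correlation). Of 23 genes in the proteases and migration list 16 rose, led by the matrix metalloproteinases MMP10 (3.36) and MMP3 (2.25), and 6 fell (camera adjusted p = 0.00442; adjusted p = 0.277 with an estimated correlation). Of 25 interferon response genes 22 rose, for example ISG15 (1.56) and MX1 (1.53), and 2 fell, STAT2 by -0.28 (camera adjusted p = 0.000154; adjusted p = 0.451 with an estimated correlation).

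Metabolic lists also moved with PDGF-BB in control cells. Of 22 cholesterol biosynthesis genes 20 rose, including SQLE (1.06), the squalene epoxidase, and IDI1 (1.03), and LSS fell (-0.29) (camera adjusted p = 1.15e-05; adjusted p = 0.22 with an estimated correlation). Of 19 glycolysis genes 17 rose, among them PFKFB4 (1.44) and the lactate transporter SLC16A3 (0.67), and 2 did not pass (camera adjusted p = 2.34e-05; adjusted p = 0.043 with an estimated correlation). Of 21 p53 targets 18 fell, among them the pro-apoptotic gene BBC3 (-1.23), TP53INP1 (-1.01) and CCNG1 (-0.99) (camera adjusted p = 7.21e-07; adjusted p = 0.043 with an estimated correlation). Of 23 ribosomal protein genes 13 fell, by at most 0.37 in RPL13, which had a log2 fold change of -0.37 (camera adjusted p = 0.0279; adjusted p = 0.67 with an estimated correlation). The call for ribosomal protein genes was lost without control replicate 3 (adjusted p = 0.15) or without control PDGF-BB replicate 3 (adjusted p = 0.0706).

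The remaining lists had members moving both ways in control cells, and camera did not separate them from the other genes. Of 24 ATF4 and amino acid response genes 14 fell and 9 rose, with CHAC1 at -1.61 and the cystine transporter SLC7A11 at 1.88 (camera adjusted p = 0.279). Of 13 G1/S and DNA replication genes 8 fell and 4 rose, with TYMS at -1.08 and RRM2 at 1.22 (camera adjusted p = 0.346), and of 7 mitosis genes 3 fell and AURKA rose (0.76) (camera adjusted p = 0.346). Of 22 TGF-beta targets 9 rose and 9 fell, INHBA by 1.85 and BAMBI by -1.70 (camera adjusted p = 0.925), and of 8 osteochondrogenic genes 4 rose, BMP2 the most (2.68), and 4 fell (camera adjusted p = 0.925). Among 5 PDGF ligands and receptors PDGFRB (0.38) and PDGFC (0.20) rose and PDGFRA (-0.19) and PDGFRL (-0.42) fell (camera adjusted p = 0.925). Markers of other cell types were few. PECAM1 of the endothelial list rose (0.79) with the other tested member not passing, and CD14 of the leukocyte list fell (-0.69). Of the others, 3 of 4 adventitial fibroblast markers fell, for example MFAP5 (-0.65), and all 3 tested epithelial markers fell, KRT18 the most (-1.84). None of the mitochondrially encoded transcripts was tested.

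In all, 6957 of 9613 genes passed the limma threshold for PDGF-BB in control cells, 3512 of them higher and 3445 lower, and 524 changed at least 2-fold, 282 up and 242 down. Adjusted over the list alone, the number of passing members was the same in 21 of the 22 lists with a tested member, and was 24 rather than 23 for the ATF4 list. With an estimated correlation, 3 of the 11 list calls held, those of YAP/TAZ targets, glycolysis and p53 targets.

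**Figure D1:**
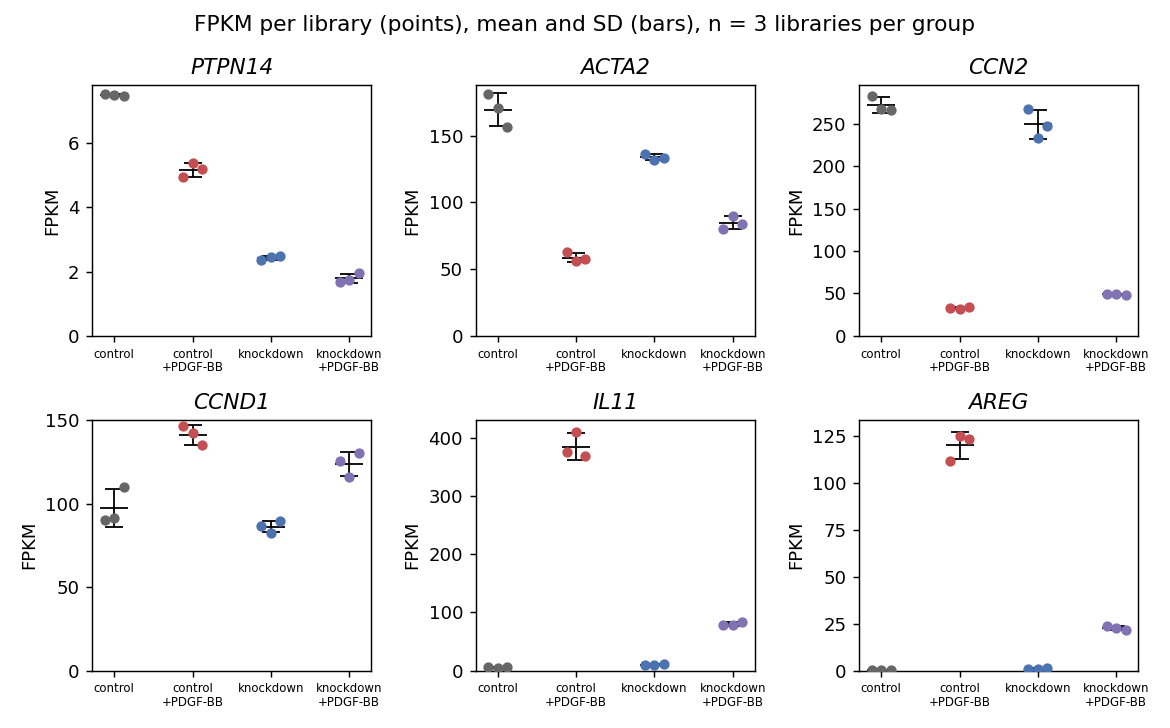
FPKM of PTPN14, ACTA2, CCN2, CCND1, IL11 and AREG (y axes, linear and starting at 0) in the 4 groups (x axes), with points for the 3 libraries of a group and bars for the mean and SD. PTPN14 is lower in all 6 knockdown libraries than in all 6 control libraries, and IL11 rises with PDGF-BB to a mean of 385 FPKM in control cells and 80.3 FPKM in knockdown cells.

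The second comparison set knockdown against control cells in the absence of PDGF-BB. Changes were smaller than those with PDGF-BB. PTGS2 rose from 12.2 ± 0.401 to 32.4 ± 4.41 FPKM (SD, n = 3; log2 fold change 1.33, SE 0.09, limma adjusted p = 5.65e-08) and EGR1 from 27.7 ± 4.13 to 69.4 ± 18.4 FPKM (SD, n = 3; log2 fold change 1.27, SE 0.13, limma adjusted p = 5.37e-06). The neuroendocrine secretory protein SCG2 (1.16), the circadian transcription repressor BHLHE40 (1.09) and the growth factor GDNF (1.08) were also among the largest rises. ADH1B fell from 82.3 ± 6.07 to 25.2 ± 3.48 FPKM (SD, n = 3; log2 fold change -1.67, SE 0.10, limma adjusted p = 2.01e-08). ASPN (-1.51), a small leucine-rich proteoglycan, the taurine transporter SLC6A6 (-1.49), the metalloproteinase inhibitor TIMP3 (-1.42) and the membrane metalloproteinase ADAM9 (-1.22) fell as well.

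Of the 20 contractile smooth muscle genes 14 fell after knockdown without PDGF-BB and SMTN rose (0.21), 18 passing when adjusted over the list alone. LMOD1 (-0.70), SYNPO2 (-0.66), ACTA2 (-0.34), CNN1 (-0.31) and TAGLN (-0.27) were among the falls (camera adjusted p = 0.000291; adjusted p = 0.475 with an estimated correlation). Glycolysis genes rose in 13 of 19 cases, also 13 adjusted over the list alone, with the glucose transporters SLC2A1 (0.50) and SLC2A3 (0.43) at the top (camera adjusted p = 5.82e-05; adjusted p = 0.104 with an estimated correlation). These were the only 2 lists called by camera in this comparison. Of the 10 splits of the 6 libraries into equal groups, 9, the real one included, called at least as many lists. The highest other split called 6, so the number of called lists does not speak against chance. Of 21 YAP/TAZ targets 7 rose, IGFBP3 (0.72) and NT5E (0.56) the most, and 4 fell, 13 passing adjusted over the list alone (camera adjusted p = 0.531). CCN2 had a log2 fold change of -0.13 (SE 0.05, limma adjusted p = 0.0546), and CCN1 of 0.08 (SE 0.09, limma adjusted p = 0.464). CCN2 passed without knockdown replicate 1 (adjusted p = 0.0127) and with the same-numbered libraries paired (adjusted p = 0.019). That pairing was picked from the same values, so the paired call is no support for a change. Of 19 Hippo pathway components 8 fell, for example STK3 (-0.32), and 2 rose, 11 passing adjusted over the list alone (camera adjusted p = 0.279). YAP1 had a log2 fold change of -0.09 (SE 0.04, limma adjusted p = 0.0948).

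Extracellular matrix genes fell in 12 of 28 cases, FBLN1 (-1.21) and MGP (-0.92) the most, and 6 rose, 18 passing adjusted over the list alone (camera adjusted p = 0.101). Cytokine and NF-kB target genes went both ways after knockdown without PDGF-BB, 8 rising, IL11 by 0.76, and 6 falling, VCAM1 by -1.41 and CCL7 by -1.21, with 15 of 23 passing adjusted over the list alone (camera adjusted p = 0.731). In the ERK list 5 of 20 genes rose, FOS (0.96) and JUNB (0.64) beside EGR1, and SPRED1 fell (-0.17), 6 passing adjusted over the list alone (camera adjusted p = 0.178). All 8 ATF4 and amino acid response genes that passed rose, SLC7A5 by 0.90 and ATF4 by 0.36, against 7 of 24 adjusted over the list alone (camera adjusted p = 0.127). In the proteases and migration list 10 genes rose, HAS2 by 0.66, and 6 fell, MMP1 by -1.10, with 18 of 23 passing adjusted over the list alone (camera adjusted p = 0.279). Of the p53 targets 5 rose, GDF15 (0.54) the most, and 7 fell, with 14 of 21 adjusted over the list alone. Of the TGF-beta targets 7 rose and 5 fell (12 of 22), of the cholesterol biosynthesis genes 3 rose and 8 fell (11 of 22), and of the osteochondrogenic genes 2 rose and 2 fell (4 of 8).

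The tables lack many members of the cell cycle lists. Of 30 members of the G1/S and DNA replication list 16 were listed and 13 tested, and of 25 members of the mitosis list 14 were listed and 7 tested. After knockdown without PDGF-BB, of 13 G1/S and DNA replication genes MCM6 (-0.25), TYMS (-0.29), CDC6 (-0.23) and CCNE1 (0.21) passed, 2 adjusted over the list alone. Of 7 mitosis genes TPX2 passed (-0.20), also 1 adjusted over the list alone. The calls of CDC6, CCNE1 and TPX2 were lost without knockdown replicate 3 or any of several other libraries. CCND1 had a log2 fold change of -0.17 (SE 0.07, limma adjusted p = 0.0642) and passed without control replicate 1 (adjusted p = 0.0344) or with the same-numbered libraries paired (adjusted p = 0.0239). The paired call is no support for a change, because the pairing was picked from the same values. Of 25 interferon response genes 2 rose, IFI6 (0.97) and IFI27 (0.61), and 3 fell, with 4 passing adjusted over the list alone. Of 23 ribosomal protein genes 1 rose and 6 fell, with 7 adjusted over the list alone. PDGFRB fell (-0.27) with PDGFRL (-0.42) and PDGFA (-0.32), the same 3 of 5 adjusted over the list alone, while PDGFRA had a log2 fold change of -0.07 (SE 0.04, limma adjusted p = 0.235). Among the markers of other cell types, PECAM1 (-0.32) and CD14 (-0.47) fell and EGFL7 (0.37) rose. The fibroblast markers SERPINF1 (-1.33), MFAP5 (-0.66) and APOD (-0.38) fell, as did the keratins KRT18 (-0.21) and KRT8 (-0.23). The call of KRT8 was lost without control replicate 3 or knockdown replicate 2, and that of EGFL7 without control replicate 1, control replicate 2 or knockdown replicate 3. In all 3913 of 9613 genes passed the limma threshold, 1872 higher and 2041 lower, of which 39 changed at least 2-fold, 11 up and 28 down. Neither of the 2 list calls held with an estimated correlation.

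The third comparison, of knockdown with control cells when both had received PDGF-BB, addressed how the stimulated state differed between the siRNA groups. AREG was lower in knockdown cells, at 22.8 ± 1.12 against 119.9 ± 7.34 FPKM (SD, n = 3; log2 fold change -2.35, SE 0.10, limma adjusted p = 8.51e-10), and IL11 was lower at 80.3 ± 3.57 against 385 ± 22.9 FPKM (SD, n = 3; log2 fold change -2.25, SE 0.09, limma adjusted p = 7.88e-10). The interstitial collagenase MMP1 was 666 ± 64.9 against 2870 ± 126 FPKM (SD, n = 3; log2 fold change -2.11, SE 0.09). Among genes with a mean log2 value of at least 3, IL33 (-1.82), RCAN1 (-1.61), a regulator of calcineurin, IL1B (-1.52) and the chemokine CXCL3 (-1.51) followed. The largest rise was in OSR1, a zinc finger transcription factor, at 20.3 ± 0.211 against 5.87 ± 0.403 FPKM (SD, n = 3; log2 fold change 1.63, SE 0.07, limma adjusted p = 7.88e-10). SCG2 (1.27), the cytochrome P450 gene CYP1B1 (1.26) and SOCS3 (1.13), an inhibitor of cytokine signalling, were next.

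Of 23 cytokine and NF-kB target genes 16 were lower in knockdown than in control cells with PDGF-BB, among them CCL20 (-1.92), and 3 were higher, CXCL12 the most (0.50), with 19 passing adjusted over the list alone (camera adjusted p = 2.23e-05). With an estimated correlation its adjusted p = 0.406. Of 22 cholesterol biosynthesis genes 15 were lower, MSMO1 (-1.10), CYP51A1 (-0.83) and IDI1 (-0.80) the most, and 2 higher, with 19 adjusted over the list alone (camera adjusted p = 2.32e-05; adjusted p = 0.406 with an estimated correlation). Of 23 proteases and migration genes 13 were lower, including MMP3 (-1.31), TIMP3 (-1.21) and MMP10 (-1.06), and 6 higher, with 21 adjusted over the list alone (camera adjusted p = 0.027; adjusted p = 0.406 with an estimated correlation). That call for proteases and migration was lost without knockdown PDGF-BB replicate 2 (adjusted p = 0.0553). Of 21 p53 targets 18 were higher, such as BBC3 (0.89), AEN (0.62) and PHLDA3 (0.55), with 19 adjusted over the list alone (camera adjusted p = 6.43e-06; adjusted p = 0.119 with an estimated correlation). Of 24 ATF4 and amino acid response genes 15 were higher, CHAC1 (1.11) and ATF4 (0.70) the most, and SLC7A11 (-1.10) and CEBPB (-0.38) lower, with 18 adjusted over the list alone (camera adjusted p = 0.00524; adjusted p = 0.406 with an estimated correlation).

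YAP/TAZ targets were higher in 13 of 21 cases and lower in 4, with 17 adjusted over the list alone. The coagulation initiator F3 (0.91), GADD45A (0.76), ANKRD1 (0.74) and CCN2 (0.58) rose the most (camera adjusted p = 0.00524; adjusted p = 0.324 with an estimated correlation). CCN1 rose by 0.34 (SE 0.09, limma adjusted p = 0.00519) and YAP1 fell by 0.19 (SE 0.04, limma adjusted p = 0.00134). Of 19 Hippo pathway components 9 were lower, SAV1 (-0.53) the most, and 6 higher, with 15 adjusted over the list alone (camera adjusted p = 0.296). ACTA2 was 84.6 ± 4.82 FPKM in knockdown against 58.7 ± 3.63 FPKM in control cells with PDGF-BB (SD, n = 3; log2 fold change 0.52, SE 0.06, limma adjusted p = 6.03e-06). CNN1 (0.23) and CNN2 (0.37) were also higher, and TAGLN had a log2 fold change of 0.09 (SE 0.05, limma adjusted p = 0.158). Over the 20 contractile genes 5 were higher and 8 lower, with 14 adjusted over the list alone (camera adjusted p = 0.46). In the ERK list 10 of 20 genes were lower, SPRY4 (-0.80), EGR3 (-0.66) and DUSP6 (-0.60) the most, and EGR1 was higher (0.58), with 11 adjusted over the list alone (camera adjusted p = 0.0614). Camera passed the ERK pathway feedback and targets without control PDGF-BB replicate 2 (adjusted p = 0.0498) or 3 (adjusted p = 0.0418), and at the threshold without knockdown PDGF-BB replicate 1. CCND1 was lower by a log2 fold change of -0.19 (SE 0.07, limma adjusted p = 0.032), a call lost without replicate 1 or 2 of either group (adjusted p = 0.132 at most).

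Of 28 extracellular matrix genes 10 were higher with PDGF-BB after knockdown, VCAN by 0.51, and 6 lower, FBLN1 by -0.67 (16 adjusted over the list alone; camera adjusted p = 0.265). Of 13 G1/S and DNA replication genes 6 were higher, CCNE1 by 0.37, and 2 lower (8 adjusted over the list alone). Of 7 mitosis genes 3 were higher, TPX2 by 0.71, and 1 lower, KIF23 (5 adjusted over the list alone). Glycolysis genes passed in 9 of 19 cases, 7 lower, ENO2 by -0.34, and 2 higher (9 adjusted over the list alone; camera adjusted p = 0.263). Of 25 interferon response genes 4 were higher, IFI6 by 0.80, and ISG20 was lower by -0.95 (4 adjusted over the list alone). Of 22 TGF-beta targets 6 were higher, TGFBI by 0.61, and 4 lower, INHBA by -1.11 (10 adjusted over the list alone). PDGFRB (-0.38), PDGFA (-0.74) and PDGFRL (-0.26) were lower and PDGFC higher (0.17), with all 5 of the PDGF list passing adjusted over the list alone. Of 8 osteochondrogenic genes 3 were lower and 2 higher (5 adjusted over the list alone), and 8 of 23 ribosomal protein genes were lower (7 adjusted over the list alone). Among markers of other cell types PECAM1 (-0.44), SERPINF1 (-0.62), MFAP5 (-0.36) and APOD (-0.49) were lower and EGFL7 (0.49) and KRT18 (0.36) higher. CD14 had a log2 fold change of -0.02 (limma adjusted p = 0.885). In all 5086 of 9613 genes passed the limma threshold, 2495 higher and 2591 lower, and 70 changed at least 2-fold, 11 up and 59 down. None of the 6 list calls held with an estimated correlation. Of the 10 splits of the 6 libraries into equal groups, 4, the real one included, called at least as many lists.

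The response to PDGF-BB within knockdown cells ran in the direction seen in control cells for most genes and was smaller for many. AREG rose from 0.943 ± 0.27 to 22.8 ± 1.12 FPKM (SD, n = 3; log2 fold change 3.62, SE 0.10, limma adjusted p = 2.59e-12), and IL24 (3.47), NR4A1 (3.29), IL11 (2.84) and IL33 (2.77) were next. ADH1B fell from 25.2 ± 3.48 to 1.33 ± 0.135 FPKM (SD, n = 3; log2 fold change -3.49, SE 0.10, limma adjusted p = 3.01e-12), and CCN2 (-2.33), PTX3 (-2.24) and THBS1 (-2.06) fell as well. ACTA2 fell from 134 ± 2.25 to 84.6 ± 4.82 FPKM (SD, n = 3; log2 fold change -0.66, SE 0.06, limma adjusted p = 3.99e-07), and TAGLN (-0.79) and CNN1 (-0.44) fell too. CCND1 rose by 0.52 (SE 0.07, limma adjusted p = 2.21e-05). Of the 9613 genes 4951 passed, 2530 higher and 2421 lower, and 209 changed at least 2-fold, 128 up and 81 down.

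All 21 YAP/TAZ targets passed in the knockdown cells, 18 falling with PDGF-BB and IGFBP3, NT5E and TGFB2 rising, also 21 adjusted over the list alone (camera adjusted p = 2.35e-07; adjusted p = 0.0468 with an estimated correlation). Of the cytokine and NF-kB targets 17 of 23 rose (18 adjusted over the list alone; camera adjusted p = 1.51e-09; adjusted p = 0.12 with an estimated correlation), led by IL11, CCL7 (2.42) and PTGS2 (2.03). Of the interferon response genes 20 of 25 rose (22 adjusted over the list alone), MX1 by 1.66 and IFIT1 by 1.62 (camera adjusted p = 2.37e-08; adjusted p = 0.356 with an estimated correlation). In the ERK list 16 of 20 genes rose, EGR3 by 1.57, and MYC fell (-0.36) (19 adjusted over the list alone; camera adjusted p = 5.27e-08; adjusted p = 0.121 with an estimated correlation). Cholesterol biosynthesis genes rose in 13 of 22 cases, SQLE by 0.53 (13 adjusted over the list alone; camera adjusted p = 0.00155; adjusted p = 0.418 with an estimated correlation). Of 21 p53 targets 15 fell, BBC3 by -0.59, and FAS rose (0.22) (17 adjusted over the list alone; camera adjusted p = 4.29e-05; adjusted p = 0.12 with an estimated correlation). Extracellular matrix genes fell in 14 of 28 cases, THBS1 and FBLN1 (-1.10) the most, and 3 rose (18 adjusted over the list alone; camera adjusted p = 0.00586; adjusted p = 0.356 with an estimated correlation). Ribosomal protein genes fell in 13 of 23 cases (15 adjusted over the list alone; camera adjusted p = 0.00261; adjusted p = 0.625 with an estimated correlation), RPS23 by -0.38. Contractile genes fell in 10 of 20 cases and rose in 6, with LMOD1 (-1.37) and TPM1 (-0.99) falling the most (16 adjusted over the list alone; camera adjusted p = 0.0663). For the contractile smooth muscle list camera passed without knockdown replicate 2 (adjusted p = 0.0427) or without knockdown PDGF-BB replicate 3 (adjusted p = 0.0381).

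Camera did not separate the remaining lists from the other genes in knockdown cells with PDGF-BB. Of 19 glycolysis genes 9 rose, PFKFB4 by 0.78, and 4 fell, ENO2 by -0.34 (14 adjusted over the list alone; camera adjusted p = 0.0665). The glycolysis list passed without knockdown replicate 2 (adjusted p = 0.0396). Of 23 genes in the proteases and migration list 12 rose, MMP10 by 2.14, and 5 fell, ADAMTS1 by -1.07 (17 adjusted over the list alone; camera adjusted p = 0.0695). That list passed without knockdown PDGF-BB replicate 2 (adjusted p = 0.0441). Of 19 Hippo pathway components 5 rose and 6 fell, VGLL3 by -1.33, and of 24 ATF4 and amino acid response genes 6 rose, SLC7A11 by 0.99, and 9 fell, CHAC1 by -0.71. Of 22 TGF-beta targets 9 rose, INHBA by 0.99, and 7 fell. Of 13 G1/S and DNA replication genes 4 rose, RRM2 by 0.68, and 4 fell, and of 7 mitosis genes AURKA rose (0.49) and 2 fell. Among the osteochondrogenic genes 3 rose, BMP2 by 1.21, and 3 fell, while PDGFRB (0.27) and PDGFC (0.27) rose and PDGFRL fell (-0.25). PECAM1 rose (0.67), and MFAP5 (-0.34), KRT18 (-1.26) and KRT8 (-0.48) fell.

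**Figure D2:**
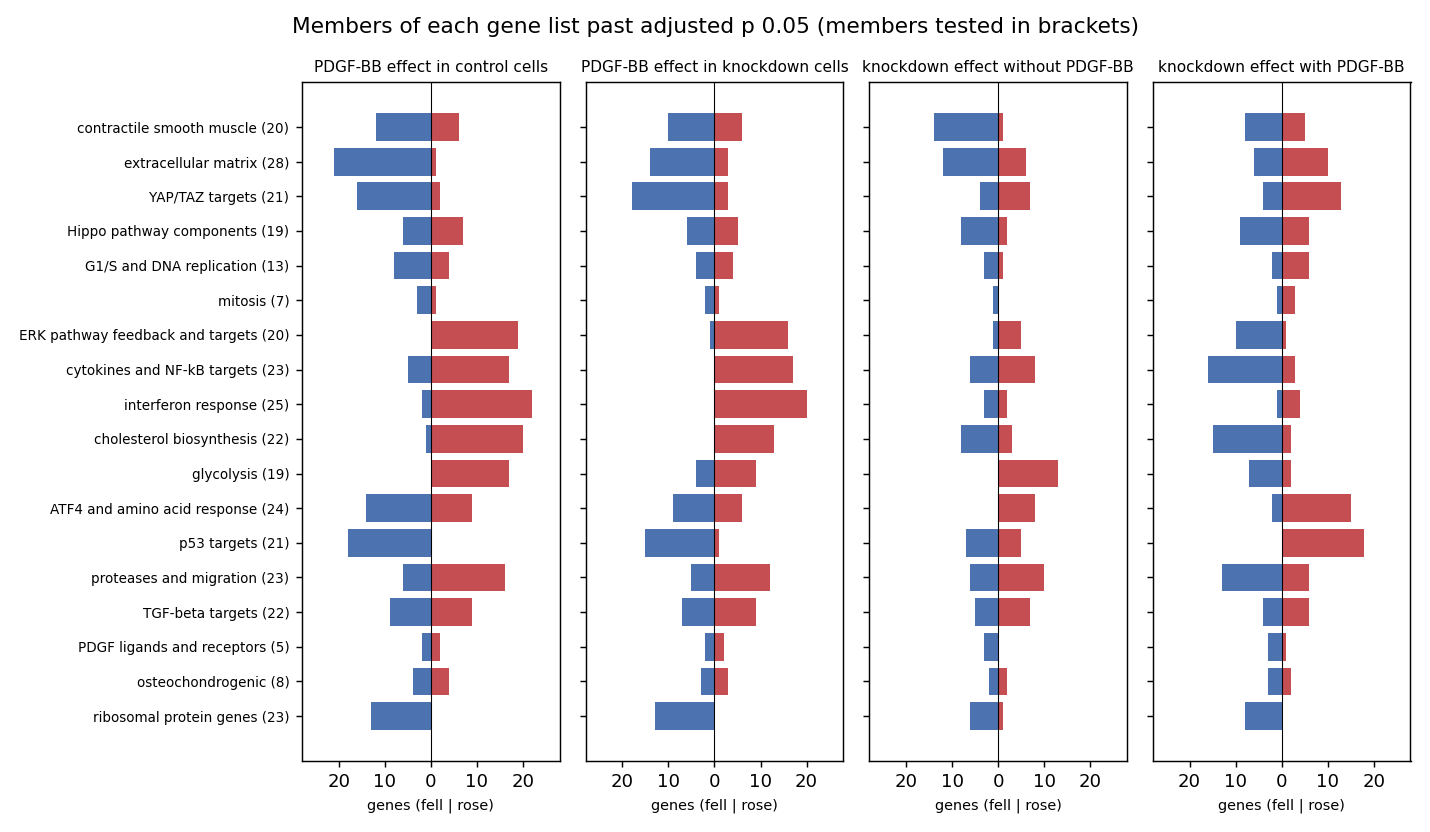
Number of members of 18 gene lists that passed the limma threshold in 4 comparisons, with genes that fell to the left of 0 and genes that rose to the right (x axes) and the number of tested members in brackets (y axis). Of the 23 cytokine and NF-kB target genes 17 rose with PDGF-BB in control cells and 16 were lower after knockdown with PDGF-BB.

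Whether knockdown changed the response to PDGF-BB was tested as an interaction, the response in knockdown cells minus that in control cells. The response of IL11 was smaller by 3.01 log2 units in knockdown cells, an interaction of -3.01 (SE 0.13, limma adjusted p = 4.34e-09), and those of AREG (-2.95), IL33 (-2.23), IL1B (-2.19) and PTGS2 (-2.17) were next in size. Positive values mean a smaller fall or a larger rise in knockdown cells. Among genes with a mean log2 value of at least 3 they were largest for the growth factor GDF5 (1.21, SE 0.09, limma adjusted p = 6.08e-07), the thioredoxin-binding protein TXNIP (1.16), the ankyrin ANK3 (1.13), the kinase ALPK2 (1.09) and the urea transporter SLC14A1 (1.05), all of which fell with PDGF-BB in control cells. ACTA2 (0.86), CNN1 (0.54), TAGLN (0.36) and CCN2 (0.71) had smaller falls in knockdown cells. Such values combine the knockdown effects without and with PDGF-BB. Without PDGF-BB, ACTA2 (-0.34), CNN1 (-0.31) and TAGLN (-0.27) were lower after knockdown, and PTGS2 (1.33) was higher. With PDGF-BB, ACTA2 (0.52), CNN1 (0.23) and CCN2 (0.58) were higher, while TAGLN did not pass (0.09, limma adjusted p = 0.158). The interaction of 0.26 for CCN1 did not pass (limma adjusted p = 0.158) unless control PDGF-BB replicate 3 was left out (adjusted p = 0.0406). The interaction was -0.10 for YAP1 (limma adjusted p = 0.221), 0.16 for PTPN14 (limma adjusted p = 0.169) and -0.02 for CCND1 (limma adjusted p = 0.897). In all 2059 of 9613 genes passed, 1049 with positive and 1010 with negative values, and 63 reached 2-fold, 13 positive and 50 negative.

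Lists with smaller rises in knockdown cells were the cytokine and NF-kB targets, with 14 of 23 negative and 6 positive (22 adjusted over the list alone; camera adjusted p = 5.71e-05; adjusted p = 0.2 with an estimated correlation), and the ERK list. In the latter 9 of 20 were negative, IER3 by -1.12 and FOS by -0.85 (11 adjusted over the list alone; camera adjusted p = 3.65e-05; adjusted p = 0.185 with an estimated correlation). After knockdown without PDGF-BB 5 of these 20, FOS and EGR1 among them, had risen and 1 had fallen. With PDGF-BB 1 was higher and 10 lower (camera adjusted p = 0.0614). The negative value of FOS thus partly reflects a level already raised without PDGF-BB. Interactions were also negative for cholesterol biosynthesis, in 13 of 22 genes, with LSS positive (15 adjusted over the list alone; camera adjusted p = 2.38e-06; adjusted p = 0.185 with an estimated correlation). Proteases and migration genes were negative in 11 of 23 cases, MMP3 at -1.54, and positive in 1 (13 adjusted over the list alone; camera adjusted p = 8.75e-05; adjusted p = 0.185 with an estimated correlation). Of 19 glycolysis genes 12 were negative, SLC16A3 (-0.43) and PFKP (-0.34) among them (16 adjusted over the list alone; camera adjusted p = 7.2e-08; adjusted p = 0.0222 with an estimated correlation). Of 21 p53 targets 14 were positive, BTG2 by 0.70 and BBC3 by 0.64 (15 adjusted over the list alone; camera adjusted p = 2.17e-08; adjusted p = 0.0222 with an estimated correlation). Contractile genes were positive in 11 of 20 cases, LMOD1 at 0.69, and SMTN was negative (13 adjusted over the list alone; camera adjusted p = 0.00148; adjusted p = 0.2 with an estimated correlation). After knockdown without PDGF-BB 14 of these 20 had fallen (median -0.26). After knockdown with PDGF-BB 5 were higher and 8 lower (camera adjusted p = 0.46), so the list was not higher in stimulated knockdown cells. Extracellular matrix genes were positive in 7 of 28 cases, THBS1 at 0.80 (12 adjusted over the list alone; camera adjusted p = 3.65e-05; adjusted p = 0.185 with an estimated correlation). YAP/TAZ targets were positive in 9 of 21 cases, GADD45A at 0.89, and negative in 4, NT5E at -0.93 (15 adjusted over the list alone; camera adjusted p = 0.0114; adjusted p = 0.185 with an estimated correlation). Of 100 groupings of the 12 libraries, the real grouping included, 30 gave at least as many called lists as these 9.

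The other lists did not pass camera for the interaction. Of 24 ATF4 and amino acid response genes 9 were positive, CHAC1 at 0.89, and 5 negative, SLC7A11 at -0.89 (18 adjusted over the list alone; camera adjusted p = 0.147). Of 25 interferon response genes 3 passed, and 0 adjusted over the list alone (camera adjusted p = 0.147). The interferon response list did pass without control replicate 3 (adjusted p = 0.0118), control PDGF-BB replicate 3 (adjusted p = 0.0374) or knockdown replicate 2 (adjusted p = 0.00134). Of 19 Hippo pathway components VGLL3 (0.59) and FRMD6 (0.59) were positive and 4 negative, WWTR1 at -0.33. Among TGF-beta targets 5 of 22 were positive and 5 negative, and among osteochondrogenic genes BMP4 (0.71) and OMD (0.74) were positive and BMP2 (-1.48) and COMP (-0.59) negative. TPX2 (0.91) of the mitosis list and TYMS (0.52) and PCNA (0.25) of the G1/S list were positive, and PDGFA (-0.42) was negative. No ribosomal protein gene passed.

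Across the 9613 genes the response to PDGF-BB in knockdown cells correlated with that in control cells at Pearson 0.90 and Spearman 0.860, a correlation across genes, which are not independent replicates. The slope of the response in knockdown cells on that in control cells was 0.590. Of the 4360 genes called in both, 4302 (98.7%) changed in the same direction and 58 in opposite directions. Of the 524 genes that changed at least 2-fold with PDGF-BB in control cells, 507 had a change of smaller size, in either direction, in knockdown cells. The interaction passed for 430 of them, 429 with a smaller or reversed change and 1, the TNF family ligand TNFSF18, with a larger rise (1.93 against 1.08), a gene singled out after its values were seen. Of all 6957 genes called in control cells 6154 had a change of smaller size in either direction. The interaction passed for 1937, 1905 with a smaller or reversed change and 32 with a larger one. Both sets were chosen by their response in control cells, which favours smaller ones in knockdown cells. The effect of knockdown without PDGF-BB correlated with that in its presence at Pearson 0.50 and Spearman 0.520 across genes. Of 2490 genes called in both 2221 (89.2%) had the same direction.

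**Figure D3:**
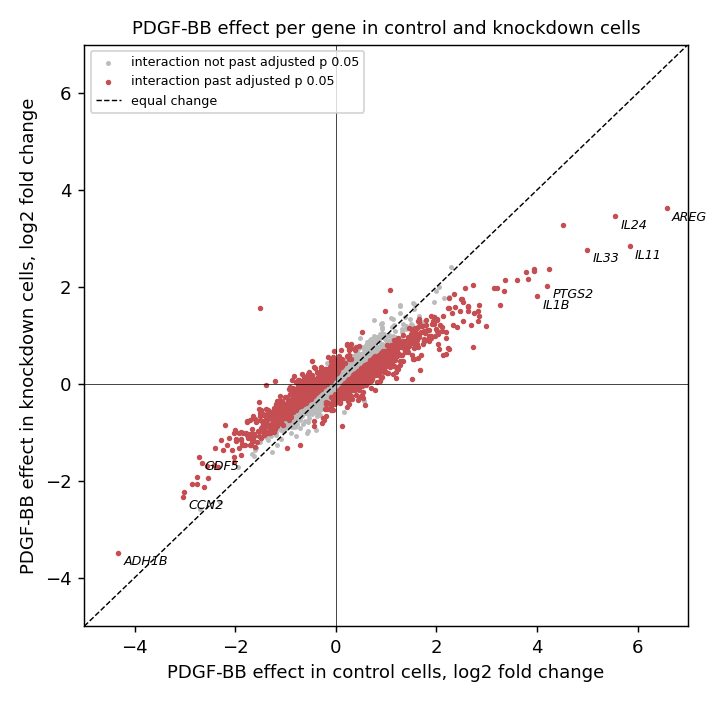
Log2 fold change with PDGF-BB of each tested gene in control cells (x axis) and in knockdown cells (y axis), with genes past the interaction threshold in red, other genes in grey and a dashed line of equal change. AREG lies at 6.58 on the x axis and 3.62 on the y axis, and ADH1B at -4.32 and -3.49.

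Genes changed by PDGF-BB in control cells were compared with genes changed by knockdown in the presence of PDGF-BB. Of the 6957 PDGF-BB genes, 3027 (43.5%) changed the other way after knockdown, 1582 having risen with PDGF-BB and being lower after knockdown, and 1445 having fallen and being higher. Changes in the same direction numbered 690, of which 324 were rises and 366 falls. Among genes with a mean log2 value of at least 3, the 5 with the largest product of both changes that rose and were then lower were AREG, IL11, IL33, IL24 and IL1B, and those that fell and were then higher were OSR1, PTX3, GDF5, PTGIS and CCN2. OSR1 fell by 2.02 with PDGF-BB (SE 0.07) and was higher by 1.63 after knockdown (SE 0.07), and PTGIS, which encodes prostacyclin synthase, fell by 2.42 (SE 0.06) and was higher by 0.78 (SE 0.06). Both comparisons use the libraries of control cells with PDGF-BB, with opposite signs, so unchanged groups already lean to opposite changes. Simulated unchanged groups gave on average 0.00 opposite changes past the adjusted p, and 55.4 opposite and 0.3 same-direction changes at the raw p limits of the data. No gene was changed in the simulation, so hardly any could pass, and it gives no baseline for the 3027. The knockdown effect with PDGF-BB is also that without it plus the interaction, so the overlap partly restates the smaller responses. Independent lists of these sizes would share 1840.7 genes of opposite and 1840.1 of the same direction. The fold changes correlated at -0.520 against -0.50 in the simulation, with a covariance of -0.0809 against a simulated -0.00264. The 3 shared libraries cannot be split into 2 parts of at least 2, so part of the excess may come from sharing them.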

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

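The tests of preselected genes, of error in the fold changes, of low-gene compression, of handling, of S phase, of shared histone reads and of library preparation were chosen only after the result was seen.

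The results below stand out because the response to PDGF-BB differed between control and knockdown cells in a test of the difference itself. The limma interaction passed for 2059 genes. Of 100 groupings of the 12 libraries 2, the real one included, called as many genes, and the other of these called 2868. The other groupings carry the treatment differences in their spread, which can lower their calls, so they do not decide whether chance can be excluded. Among genes with a mean log2 value of at least 3, negative interactions were largest for IL11 (-3.01), AREG (-2.95), IL33 (-2.23), IL1B (-2.19) and PTGS2 (-2.17), and positive ones for GDF5 (1.21), TXNIP (1.16), ANK3 (1.13), ALPK2 (1.09) and SLC14A1 (1.05). ACTA2 (0.86), CNN1 (0.54), TAGLN (0.36) and CCN2 (0.71), named in advance, also passed.

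By camera the lists of contractile smooth muscle (adjusted p = 0.00148), extracellular matrix (adjusted p = 3.65e-05), YAP/TAZ targets (adjusted p = 0.0114) and p53 targets (adjusted p = 2.17e-08) had positive interactions, of which p53 targets alone held with an estimated correlation (adjusted p = 0.0222). The lists of ERK pathway feedback and targets (adjusted p = 3.65e-05), cytokines and NF-kB targets (adjusted p = 5.71e-05), cholesterol biosynthesis (adjusted p = 2.38e-06), glycolysis (adjusted p = 7.2e-08) and proteases and migration (adjusted p = 8.75e-05) had negative ones. With an estimated correlation glycolysis alone of these held (adjusted p = 0.0222). The other 7 of both directions were lost, with adjusted p = 0.185 for extracellular matrix, YAP/TAZ, ERK, cholesterol and proteases and 0.2 for contractile genes and cytokines. Of 100 groupings of the 12 libraries 30, the real one included, gave as many as these 9 lists, with up to 11 in the others, and as they carry the treatment differences they do not decide on chance.

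Smaller responses to PDGF-BB in knockdown cells are the first pattern. Error in the fold changes argues poorly for it, since the slope of 0.590 became 0.601 after correction for error, and the slope among the 1964 genes with a mean log2 value of at least 5 was 0.599, so compression of low genes by the pseudocount is not the whole cause. At the fitted spread, a loss of the same proportion in every gene is argued against by the 524 genes with at least 2-fold change. Of these 25.4% (133 genes, SE 1.9 with genes taken as independent) departed from the common slope by over 3 standard errors, where chance gives 0.9%. A fitted spread that is too small, or the pseudocount in genes with low FPKM, would also raise that share, so such a loss is not excluded. Treatment or handling that differed between the siRNA groups cannot be told apart from the knockdown, because each siRNA was given as a group. It could lie behind any of the 429 genes with a smaller or reversed change by the interaction. A smaller change can also reflect levels that knockdown had already moved without PDGF-BB, which the interaction does not separate. Of 19 glycolysis genes 13 rose after knockdown without PDGF-BB (median 0.20), and 7 were lower and 2 higher with it (median -0.07). Of 21 p53 targets 5 rose and 7 fell without PDGF-BB (median -0.10), and 18 were higher with it (median 0.25). An effect of lower PTPN14 on PDGF-BB signalling is the biological explanation that the design names, and it stays open as a hypothesis. No sample separates lower PTPN14 from any other effect of the PTPN14 siRNA, so these cannot be told apart either.

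A second pattern is that nearly all tested genes differed between the 4 groups. Only 0.31% of them (30 genes) had an overall p over 0.5, where unchanged genes would give 50%, and 91.8% had a p under 0.05. A spread between libraries that is too small cannot be told apart from this. In 99 other groupings of the 12 libraries 49.3% of genes lay over 0.5 on average, but such groupings carry the treatment differences in their spread, which fixes that outcome. A candidate explanation is that the listed genes had been chosen for differing between the groups before the tables were made, which would make the share of changed genes larger than among all genes and the p-values adjusted over the listed genes too small. Of 77 cytosolic ribosomal protein genes 10 are not listed, although the listed ones have a median mean of 452 FPKM, so the table lacks genes of a class that is abundant. What removed them was not tested, and a strong effect of both treatments on most expressed genes stays open.

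The third pattern is that histone transcripts were higher after knockdown, in 14 of 17 genes without and 16 of 17 with PDGF-BB, with medians of 0.61 and 0.72, a list chosen after its values were seen. More cells in S phase cannot be told apart. In the G1/S and DNA replication list 0 of 13 genes rose by the histone median, but how far they would need to rise is not known. With PDGF-BB 6 were higher against 2 lower (median 0.15) and TPX2 rose by 0.71. Without PDGF-BB 1 was higher against 3 lower (median 0.08) and TPX2 was lower, although the histone transcripts rose there too. Reads shared by the 2 histone genes with identical values, H2AC18 and H2AC19, are not the whole cause, the lower of the medians without them being 0.55 over 15 genes. Library preparation that differed between the siRNA groups, for example in the capture of transcripts without a poly(A) tail, cannot be told apart from the knockdown for the 14 genes, because no sample crosses the groups. An effect of lower PTPN14 on histone transcripts remains open and untested, and no sample separates it from other effects of the PTPN14 siRNA.

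For the pairwise comparisons, 3 libraries against 3 allow 10 splits, too few for a share under 0.05. For the number of genes, 1 split of 10, the real one, reached the real value in each comparison, with 6957, 3913, 5086 and 4951 genes and 0 genes in the highest other split. Of the splits for knockdown without PDGF-BB, 4 part all 3 same-numbered pairs, and the other such splits gave 0 genes and at most 6 lists, as did those that keep a pair together. For the number of lists, 1 of 10 splits gave as many as the 11 for PDGF-BB in control cells (9 in the highest other), 9 of 10 as many as the 2 for knockdown without PDGF-BB (6), 4 of 10 as many as the 6 for knockdown with PDGF-BB (7) and 2 of 10 as many as the 8 for PDGF-BB in knockdown cells (8). For the 3027 opposite changes, 2 of 100 groupings of the 9 libraries, the real one included, gave as many, the highest other giving 4292. These groupings also carry the treatment differences in their spread and decide nothing on chance.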

How the results depend on the processing

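The pseudocount of 0.1, the adjustment over all protein-coding genes and the block for the libraries without PDGF-BB only were chosen after the data were seen, while the other alternatives were planned. No result reversed. Requiring at least 2-fold lowered the number of genes to 524 for PDGF-BB in control cells, 39 for knockdown without PDGF-BB, 70 for knockdown with PDGF-BB, 209 for PDGF-BB in knockdown cells and 63 for the interaction, as a stricter threshold must. With an estimated correlation camera called 3, 0, 0, 1 and 2 lists in the same order, in place of 11, 2, 6, 8 and 9. By fry, which tests whether a list's genes move one way and not against other genes, 7 lists passed for knockdown without PDGF-BB, 14 for knockdown with PDGF-BB and 14 for PDGF-BB in knockdown cells. An adjusted p under 0.01 in both comparisons left 2014 opposite changes. Across genes with a mean log2 value of at least 3 the correlation was 0.918 for the response to PDGF-BB and 0.539 for the knockdown effect, against jackknife standard errors of 0.011 and 0.025.

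The other settings kept each number of genes within 1.5 times its value. Leaving out single libraries gave 6412 to 6618 genes for PDGF-BB in control cells, 2990 to 3748 for knockdown without PDGF-BB, 4227 to 4814 with it, 4283 to 4723 for PDGF-BB in knockdown cells, 1579 to 2030 for the interaction and 2462 to 2903 opposite changes. With the adjustment over all protein-coding genes the numbers were 6392, 3218, 4318, 4264 and 1498. Of 477 results for named genes, 13 were lost with that adjustment, 35 were lost and 4 gained in at least 1 fit without a library, 2 were lost with median-ratio scaling, 4 without the filter and 3 with the pseudocount of 0.1. CCND1 after knockdown with PDGF-BB is among the lost ones, at -0.14 in the weakest fit without a library, and the cause was not tested. Leaving out control replicate 1 or knockdown replicate 3 also added the ATF4 and amino acid response list, and leaving out knockdown replicate 2 the extracellular matrix list, for knockdown without PDGF-BB. The ribosomal protein genes were added for knockdown with PDGF-BB without knockdown PDGF-BB replicate 1.

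Over all 12 libraries the replicate numbers do not pair the libraries. The 18 same-numbered pairs correlated in their deviations at -0.225 to 0.255 (median 0.018, other pairs -0.007), and 5 of 12 libraries correlated best with their own number. With a replicate block the numbers of genes were 6916, 3877, 5052, 4926 and 2011, and those of opposite changes 2984. Of the 477 results for named genes 1 was gained (CCN2 after knockdown without PDGF-BB) and 3 no longer passed for the interaction (MGP, STAT2 and KRT8). A replicate block for the libraries without PDGF-BB only was fitted because their same-numbered pairs correlated in their deviations. With that block knockdown without PDGF-BB had 4189 genes and 2 lists, and PTPN14 was at -1.31. Of 95 named genes the calls of CCN2 and CCND1 were gained and no other changed. That pairing was picked from the same values, which can lower the spread by itself. Libraries of unlike number also correlated, as control PDGF-BB replicate 1 did with knockdown replicate 3 (0.273). The gained calls are therefore no support for these changes. Methods for read counts had been planned as alternatives and were not run, because the tables hold FPKM. Depth is unknown, so what it limits cannot be stated.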

Other observations

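The tests of the 5 lists below were chosen, and FST, SULT1A4 and VCAM1 singled out, only after the result was seen.

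Genes of antigen presentation by HLA class I were higher after knockdown. Without PDGF-BB 11 of 17 such genes rose and 2 fell, HLA-B from 682 ± 11.1 to 1228 ± 26.2 FPKM (SD, n = 3; log2 fold change 0.85, SE 0.05) and the peptide transporter TAP1 by 0.45 (camera adjusted p = 3.01e-05; adjusted p = 0.0301 with an estimated correlation). With PDGF-BB 15 rose and ERAP2, a peptide-trimming enzyme, fell (-0.11) (camera adjusted p = 1.53e-06; adjusted p = 0.0155 with an estimated correlation). Histone transcripts rose in 14 of 17 genes without PDGF-BB (camera adjusted p = 3.05e-09; adjusted p = 0.000787 with an estimated correlation), and in 16 of 17 with it (camera adjusted p = 2.24e-07; adjusted p = 0.00182 with an estimated correlation). Histone and HLA class I genes have near-identical family members, so their single values are uncertain. Kinases and SR proteins that regulate splicing were lower in 8 of 14 genes without PDGF-BB, RSRP1 by -1.48 and CLK1 by -1.07, and higher in 1 (camera adjusted p = 0.00063; adjusted p = 0.0752 with an estimated correlation), and in 11 of 14 with it (camera adjusted p = 5.88e-05; adjusted p = 0.0411 with an estimated correlation). All of these lists include genes already seen among the largest knockdown changes, such as HLA-F, the histone gene H2BC5 and RSRP1. Their camera p-values therefore partly restate those changes.

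Ligands of the EGF receptor family moved with AREG. All 5 tested (AREG, EREG, HBEGF, NRG1 and EPGN) rose with PDGF-BB in control cells (camera adjusted p = 0.000177; adjusted p = 0.101 with an estimated correlation), EREG from 35.9 ± 4.15 to 262 ± 27.9 FPKM (SD, n = 3). Their interactions were all negative, -2.95 for AREG, -1.33 for EREG, -0.58 for HBEGF, -0.55 for NRG1 and -0.46 for EPGN (camera adjusted p = 8.85e-07; adjusted p = 0.0326 with an estimated correlation). The list was made after the change of AREG was seen and includes it, so these camera p-values partly restate that change. Of 5 metallothioneins, which bind zinc and copper, 4 rose after knockdown with PDGF-BB, MT1E by 1.12 (camera adjusted p = 0.0235; adjusted p = 0.213 with an estimated correlation). MT1E was itself among the largest rises, so these p-values partly restate it. The values of metallothioneins are uncertain because they have near-identical family members.

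FST, which encodes the activin antagonist follistatin, rose with PDGF-BB in control cells from 24.0 ± 0.934 to 36.3 ± 0.816 FPKM and fell in knockdown cells from 22.2 ± 1.76 to 16.2 ± 0.406 FPKM (SD, n = 3; log2 fold changes 0.58 and -0.43, interaction -1.01, limma adjusted p = 1e-06). SULT1A4, which has the near-identical copy SULT1A3 and is therefore uncertain, fell by 1.51 in control cells and rose by 1.58 in knockdown cells (SE 0.56 each, interaction 3.09, SE 0.79, limma adjusted p = 0.012). VCAM1, the adhesion receptor of leukocytes, was 3.25 ± 0.152 FPKM in control cells and 0.617 ± 0.0643, 0.603 ± 0.0896 and 0.587 ± 0.104 FPKM in control cells with PDGF-BB, knockdown cells and knockdown cells with PDGF-BB (SD, n = 3). All but the control group lie under the minimum of 1 FPKM, where a further fall could hardly be seen.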
